A study of Mus musculus with 4 samples.

How the data were processed

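5-Hydroxymethylcytosine (5hmC), the base that TET enzymes make by oxidising 5-methylcytosine, was measured in LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive bone marrow fraction that holds blood stem and early progenitor cells. Cells came from 2 wild type and 2 Tet1 knockout mice aged 6 months, with 1 library per mouse. Per the labels' protocols, genomic DNA was cut in separate reactions with HpaII and MspI, a pair of enzymes that recognise the same CCGG sequence but differ in their sensitivity to cytosine modification. Adapters were ligated to the cut ends, a short tag beside each cut was released with EcoP15I, and the tags were amplified by in vitro transcription and PCR before Illumina sequencing. The labels call the assay HELP-GT. In this method, as generally described, a glucosyltransferase adds glucose to 5hmC and so protects the site from MspI. The genome build was mm9, per the submitters' processing notes. The aligner, the counting of tags and the formula of the score are not given in the sources used here.

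Each library came with 1 file holding a chromosome, a position and a score from 0 to 100 for the same 9738 sites. The authors deposited the score without a stated unit or direction, so whether a low or a high score means more 5hmC is not given in the sources used here. The values themselves show part of its construction. Many scores equalled 200/π times the arctangent of a library constant multiplied by a ratio of whole numbers no larger than 10. Within a tolerance of 0.001 score units this held for 24.9% and 21.9% of the scores between 0 and 100 in wild type replicates 1 and 2. It held for 24.7% and 15.6% in knockout replicates 1 and 2. With 200 constants drawn at random the median share was at most 0.0524% in any library and the highest share 17.1%. The constants, which are fixed only up to a simple ratio and are stated here between 1 and 2, were 1.58, 1.39, 1.46 and 1.46 in the same order. Judged from these values, the score is built as an angle and was not read as a percentage of molecules. Depth per site is unknown, and no counts were inferred from the scores. Because depth is unknown, the precision of a single score cannot be given. Blank scores occurred at 11, 47, 18 and 37 sites in wild type replicates 1 and 2 and knockout replicates 1 and 2, and the 9633 sites scored in all 4 libraries were used for comparisons.

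The listed sites follow a rule on these same scores, found from the values and not stated in the sources used here. All 9738 sites scored below 50 in both libraries of at least 1 genotype, and no site broke this rule. Under either other way of parting the 4 libraries into pairs, 3608 sites would have broken it. Other criteria behind the list are not given in the sources used here. Sites that scored 50 or more in a library of each genotype were not analysed here.

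Library means, medians and shares were compared with an exact two-sided permutation test of 2 libraries against 2, whose smallest possible p is 0.333. Single sites were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided) on the untransformed scores, with Benjamini-Hochberg adjustment and a threshold of 0.05. These tests treat the listed sites as given and take no account of how the list was chosen. The fit was tested on simulated data with the real site means and residual variances over 9633 sites, of which 50 each were shifted by 20, 40, 60 and 80 score units. Simulated scores were not held within 0 to 100. Median estimated shifts were 18.8, 38.4, 59.8 and 80.1. No shifted site passed the adjusted threshold at any size, and 25, 37, 45 and 46 of 50 passed an unadjusted p of 0.05, with 0 false calls after adjustment. To measure what the listing rule gives without site-specific differences, 20 sets of sites were drawn in which the 4 libraries vary independently and only sites meeting the rule are kept. Each library kept its own scores and its own share below 50, so the draws also carry library-wide differences between genotypes. Run means were tested with the same limma fit over 46 runs. On simulated run means with 23 of 46 runs shifted by 20 score units, a mean of 14.9 shifted runs over 200 draws passed the adjusted threshold, with a mean of 0.545 false calls. Runs of the same sizes were also built from sites drawn under the listing rule in 1000 draws, with each site of a run drawn independently of its neighbours. Means by chromosome were compared between genotypes with each library's value, and each chromosome's difference was set against the other sites by permuting chromosome labels over sites 100000 times, with Benjamini-Hochberg adjustment over 20 chromosomes. Correlations of neighbouring sites were set against 10000 random pairings, with intervals from 2000 bootstrap draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the other steps. Shares of sites carry 95% Wilson intervals, which cover counting error over sites only.

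The comparisons of library levels, of the share above 0, of single sites with limma, of direction and of chromosome means, with the exact test of 2 against 2, the rule for named sites and most alternatives were fixed before the data were examined. Those alternatives were leaving out each library, the mouse number as a block, quantile normalization, median centring, a log2 scale, eBayes without a trend, a filter on scores of 0, a threshold of 0.10, a trimmed mean, a higher floor and the autosomes alone. The following were added after the data were seen: the listing rule and its simulation, the counts of sites below 50, the permutation of chromosome labels, the spread and extreme scores on X, Fisher's exact tests, runs of neighbouring sites and their test, correlations of neighbouring sites, the shift sizes of the simulated data, a single library constant (the geometric mean, 1.47) and its simple ratios per library, the log2 scale on sites above 0 alone, and the site tests without X and Y. The rule took the 12 largest mean decreases and the 12 largest mean increases among sites that passed, completed from sites where both knockout scores lay beyond both wild type scores and the mean difference exceeded both gaps between replicates. It also took the 3 Tet genes and 1 member of each gene list, and allowed at most 4 sites known by position alone. As no site had a gene name here, that limit left 4 sites, and taking 2 from each direction was decided after the data were seen. The gene table used here follows another build, GRCm38, and 3 listed sites on chromosome 1 lie beyond its last gene there. Sites were therefore given by mm9 position only. The 12 gene lists fixed beforehand, the Tet genes, Tet1 included, and the promoter and gene-body classes were not analysed here.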

Results

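The study asked how loss of Tet1, one of the enzymes that oxidise 5-methylcytosine to 5hmC, changes hydroxymethylation in LSK cells of 6-month-old mice. Scores at 9738 CpG-containing restriction sites were available for 2 wild type and 2 Tet1 knockout mice. The list covered all 19 autosomes, the X chromosome and 5 sites on the Y chromosome, and the median distance between listed neighbours was 74907 bp. The direction of the score with respect to 5hmC is not stated in the sources used here, so results are given as scores. A score of exactly 0 was given at 89 and 61 sites in wild type replicates 1 and 2 and at 52 and 136 sites in knockout replicates 1 and 2, and a score of exactly 100 at 18, 37, 26 and 28 sites in the same order. The list itself follows a rule on these scores, with every listed site below 50 in both libraries of at least 1 genotype, so differences at listed sites are not independent evidence of a difference between genotypes. The depth behind each score is unknown.

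**Figure D1:**
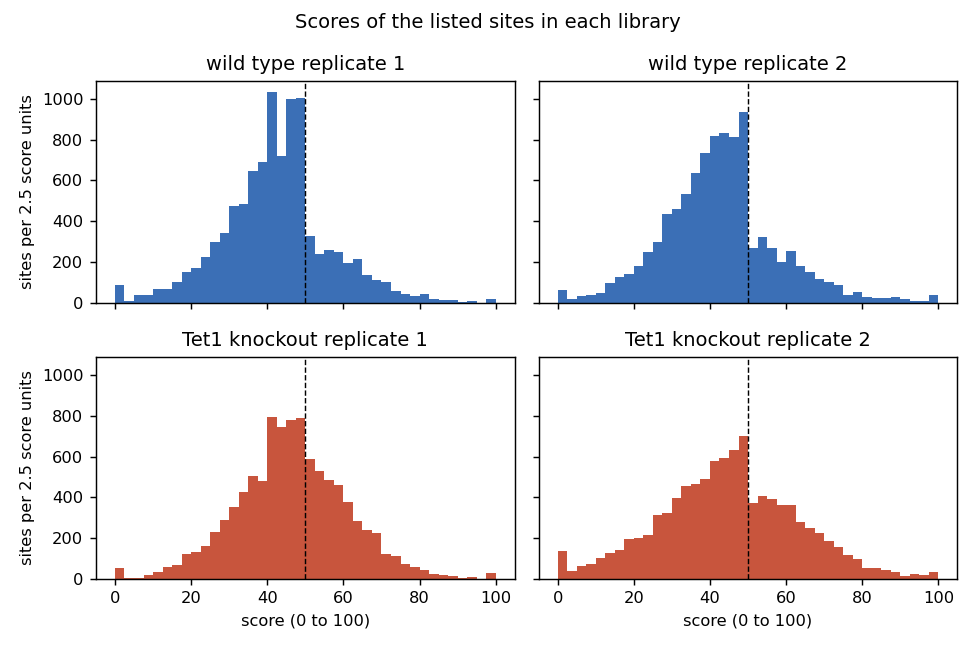
Number of listed sites (vertical axis, per 2.5 score units) by score (horizontal axis, 0 to 100) in each of the 4 libraries, with a dashed line at 50. The number of sites drops at 50 in all 4 libraries, from 2008 sites scoring 45 to 50 to 569 scoring 50 to 55 in wild type replicate 1 and from 1570 to 1117 in knockout replicate 1.

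Scores were higher in the knockout than in the wild type over the listed sites as a whole. The mean score was 42.6 ± 0.155 in the wild type and 45.7 ± 1.21 in the knockout (SD, n = 2 mice each), a difference of 3.15 score units. The gap between the wild type libraries was 0.219 and that between the knockout libraries 1.70, so both knockout means lay above both wild type means. Median scores differed by 3.25 in the same direction. The exact two-sided permutation test gave p = 0.333 for the mean and for the median, the smallest value that 2 libraries against 2 can reach. Scores below 50 were more frequent in the wild type, at 78.6% (95% Wilson interval 77.8 to 79.4) and 77.2% (76.3 to 78.0) of the scored sites in replicates 1 and 2. The knockout libraries had 62.1% (61.1 to 63.0) and 64.2% (63.2 to 65.1). Because sites were listed by scores below 50 in these same libraries, these shares, means and medians do not estimate a difference over unselected sites. Nearly all sites scored above 0, with 99.1% (98.9 to 99.3) and 99.4% (99.2 to 99.5) in the wild type and 99.5% (99.3 to 99.6) and 98.6% (98.3 to 98.8) in the knockout. This share differed by less than the gap between the knockout libraries (exact permutation p = 1). The difference, -0.145 percentage points, was 0.353 without knockout replicate 2.

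Sites that scored below 50 in 1 genotype alone were more often wild type sites than knockout sites. Of the 9633 sites scored in all libraries, 2223 (23.1%) were below 50 in both wild type libraries and in neither knockout library. The reverse held for 1331 sites (13.8%). A further 2697 sites (28.0%) were below 50 in both wild type libraries and 1 knockout library, 1604 (16.7%) in both knockout libraries and 1 wild type library, and 1778 (18.5%) in all 4. Both wild type libraries were thus below 50 at 6698 sites and both knockout libraries at 4713. The remaining 9 of the 16 possible patterns were absent, as the listing rule requires. The counts depend on the number of libraries asked for. Without knockout replicate 1 or 2, 3466 or 3677 sites were below 50 in the wild type alone, and without wild type replicate 1 or 2, 2210 or 2056 were below 50 in the knockout alone. Had the libraries varied independently of one another, with the same library-wide shares and the same rule, 1998 sites would have been below 50 in the wild type alone and 1012 in the knockout alone. Those shares were fitted to these same counts, so the model is not an independent expectation. The observed 7 counts departed from that model (deviance 597 on 2 degrees of freedom). A second model added a term for the patterns in which replicates agree within both genotypes: all 4, wild type alone and knockout alone. This term, called a shared site level here, cannot separate a level shared by all 4 libraries from site-specific genotype differences. The model gave 2326 sites below 50 in the wild type alone and 1228 in the knockout alone. The counts departed from this model as well (deviance 54.3 on 1 degree of freedom).

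**Figure D2:**
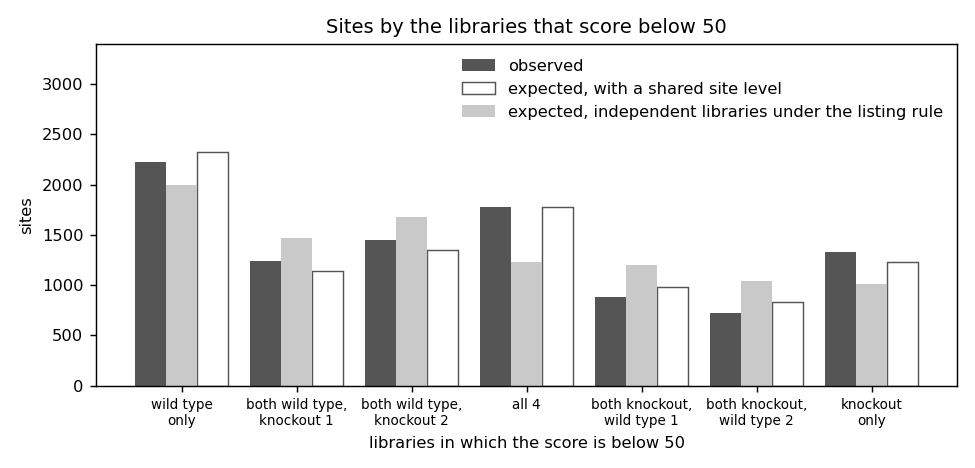
Number of sites (vertical axis) by the libraries in which the score was below 50 (horizontal axis), observed (dark bars), expected for independent libraries under the listing rule (light bars) and expected with a shared site level (open bars). The open bars add a term for replicates agreeing within both genotypes, which cannot separate a shared level from site-specific genotype differences. More sites were below 50 in the wild type libraries alone (2223) than in the knockout libraries alone (1331), and the wild type count lies above the expectation for independent libraries (1998) and below that with a shared site level (2326). The knockout count lies above both expectations (1012 and 1228).

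No single site passed the test between genotypes. With limma, 0 of 9633 sites were higher and 0 lower in the knockout at an adjusted p of 0.05, and the smallest adjusted p was 0.118. The adjusted test also passed 0 of 50 simulated sites shifted by 80 score units, so the lack of calls does not show that sites were alike. At an unadjusted p of 0.05, 1364 sites were higher and 785 lower in the knockout, where 482 in all would be called by chance. The split turned with centring: after median centring 928 were higher and 1052 lower, and after quantile normalization 803 were higher and 1223 lower. The listing rule and library-wide differences together raise such counts without site-specific differences. Simulated independent libraries under the rule gave a mean of 1846 sites (range 1771 to 1947 over 20 draws), against 2149 observed. At an adjusted p of 0.05 the same draws gave a mean of 2.85 sites (range 0 to 13), against 0 observed. On a log2(score + 1) scale limma with Benjamini-Hochberg adjustment called 248 sites higher and 152 lower in the knockout.

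Both knockout scores lay above both wild type scores at 3290 sites (34.2%) and below both at 2024 sites (21.01%). Parted by replicate number, both replicates 2 lay above both replicates 1 at 9.04% of sites and below both at 12.9%. In the crossed parting, wild type replicate 2 and knockout replicate 1 both lay above the other two libraries at 12.8% of sites and below them at 10.1%. Chance for unselected sites gives 16.7% in each direction. Simulated independent libraries under the listing rule, which carry the library-wide differences, gave a mean of 33.1% higher and 20.9% lower. The excess of higher over lower sites, 13.1 percentage points, was 3.89 points after median centring. Across sites, Pearson's r was 0.174 between the wild type libraries and 0.229 between the knockout libraries, and ran from -0.148 to -0.0735 between libraries of different genotype. Sites are not independent replicates. The simulated libraries under the rule gave means of 0.165 (range 0.143 to 0.185) between wild type libraries and 0.181 (0.167 to 0.197) between knockout libraries. For the mean r between genotypes they gave -0.227 (-0.234 to -0.219), against -0.116 observed. The observed knockout and between-genotype values thus lay outside all 20 draws, and the wild type value inside.

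The named sites had the largest mean differences in each direction among sites where both knockout scores lay beyond both wild type scores. The site at position 48899180 of chromosome 13 (mm9) scored 82.5 and 100 in the wild type and 13.7 and 3.25 in the knockout, a difference of -82.8 ± 8.84 (SE, limma). The site at position 86865421 of chromosome 8 scored 80.4 and 100 in the wild type and 18.1 and 9.20 in the knockout, a difference of -76.6 ± 8.78. In the other direction, the site at position 111451924 of chromosome 12 scored 14.1 and 30.7 in the wild type and 100 in both knockout libraries, a difference of 77.6 ± 8.65. The site at position 58726151 of chromosome 4 scored 37.8 and 14.5 in the wild type and 100 in both knockout libraries, a difference of 73.8 ± 10.1. Each named site held a score of exactly 100, the top of the scale, in some library. Equal scores of 100 in both knockout libraries therefore do not measure the spread between these mice. All 4 had a limma adjusted p of 0.118 and did not pass the threshold, which simulated sites shifted by 80 score units did not pass either. In all, 4110 sites had both knockout scores beyond both wild type scores by a mean difference larger than both gaps between replicates, 2534 of them higher and 1576 lower in the knockout.

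Runs of neighbouring sites gave mean scores over several positions of 1 locus. There were 46 runs of at least 3 listed sites with no gap above 1000 bp, holding 156 sites, and limma on the run means called 5 runs higher and 1 lower in the knockout at an adjusted p of 0.05 (7 and 6 at an unadjusted p of 0.05). On chromosome 8, 3 sites from 3517391 to 3517838 averaged 38.7 and 44.0 in the wild type and 60.01 and 65.8 in the knockout, a difference of 21.5 ± 3.22 (SE). On chromosome 3, 4 sites from 95044213 to 95045651 averaged 38.5 in both wild type libraries and 57.8 and 60.5 in the knockout. On chromosome 15, 3 sites from 78503388 to 78503624 averaged 37.3 and 42.9 in the wild type and 59.1 and 60.6 in the knockout. The other 2 runs called higher lay on chromosome 5 from 103456061 to 103456219, with a difference of 14.7 ± 2.10, and on chromosome 4 from 145722577 to 145723021, with a difference of 9.49 ± 1.71. All sites of these 5 runs were higher in the knockout. The run called lower, 3 sites on chromosome 11 from 114036915 to 114037143, averaged 61.1 and 58.8 in the wild type and 44.97 and 44.999 in the knockout, although 1 of its 3 sites was higher in the knockout. The calls depend on the setting and on the list. The simulated runs drew each site independently, whereas genotype differences at real neighbours no more than 200 bp apart were correlated (r = 0.191). Their counts may therefore not match what the rule gives for real runs. Leaving out any 1 of the 4 libraries or fitting limma without a trend called 0 runs, median centring called 0 higher and 1 lower, quantile normalization called 3 higher and 4 lower, and simulated independent libraries under the listing rule gave at least 6 called runs in 50 of 1000 draws.

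Larger decreases in mean did not pass the test. On chromosome 9, 3 sites from 105863137 to 105863940 averaged 53.9 and 74.0 in the wild type and 40.8 and 31.2 in the knockout. On chromosome 5, 3 sites from 116532965 to 116533228 averaged 52.2 and 63.7 in the wild type and 40.2 and 33.5 in the knockout. These runs and the next were chosen after their values were seen. The longest run by number of sites, 7 on chromosome 13 from 59579217 to 59579452, differed more between wild type mice (13.0 and 60.9) than between genotypes. Both knockout run means lay above both wild type run means in 12 of the 46 runs and below both in 12. Simulated libraries under the listing rule, with the sites of a run drawn independently, gave a mean of 15.5 runs above (95% of draws 9 to 22) and 7.01 below (3 to 12). Chance for unselected sites gives 16.7% in each direction.

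By chromosome, the knockout mean exceeded the wild type mean on all 19 autosomes, and on each of them both knockout libraries lay above both wild type libraries. The difference ran from 2.02 score units on chromosome 12 to 5.75 on chromosome 14, where the wild type averaged 41.3 ± 0.319 and the knockout 47.0 ± 2.13 (SD, n = 2). All 19 autosomes also had more sites below 50 in the wild type alone than in the knockout alone, with 2190 against 1293 sites in total. The autosomes share the same 4 libraries and any library-wide shift, so the 19 are not separate replicates of the difference. The X chromosome departed from the autosomes. Over its 189 sites the wild type averaged 44.5 and 46.5 and the knockout 45.6 and 40.9, a difference of -2.24. The X difference minus the autosome difference was -5.50 (two-sided permutation of chromosome labels over sites, p = 6e-05, Benjamini-Hochberg adjusted p = 0.0012 over 20 chromosomes), and no autosome had an adjusted p under 0.05. Sites are the unit of that test. With libraries as the unit, the exact permutation test of 2 against 2 gave p = 0.333. Without knockout replicate 2 the X difference was 0.0924, while the gap to the autosomes was -3.99. Sites below 50 in 1 genotype alone numbered 33 for the wild type and 38 for the knockout on X (Fisher's exact test against the autosomes, two-sided p = 0.0061).

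**Figure D3:**
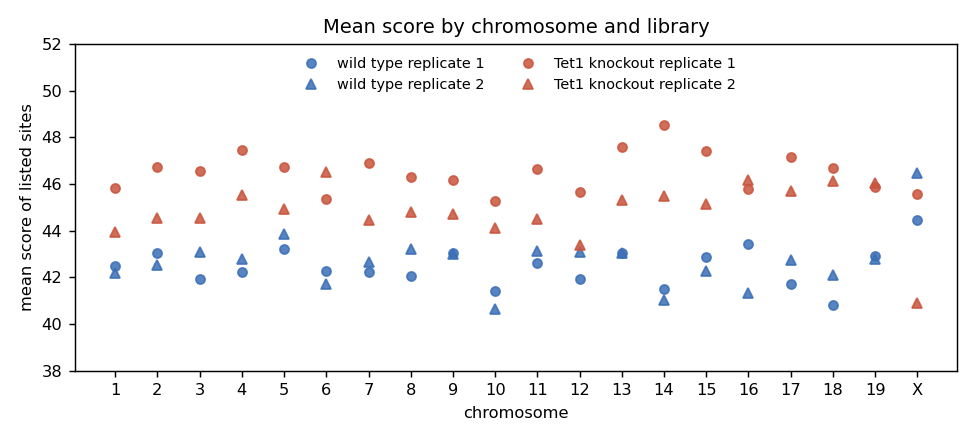
Mean score of the listed sites (vertical axis, score units, axis from 38 to 52) on each autosome and X (horizontal axis) in the 4 libraries, each a point. Both knockout libraries lie above both wild type libraries on the 19 autosomes, and on X knockout replicate 1 (45.6) lies between the wild type libraries (44.5 and 46.5).

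The spread of scores on X also lay apart by genotype in these 4 libraries. In the wild type the SD over X sites was 19.3 and 20.6, against 14.2 and 14.9 over autosomal sites, ratios of 1.36 and 1.38. In the knockout it was 11.7 and 14.3 against 14.6 and 18.3, ratios of 0.803 and 0.782. The same ratio for single autosomes ran from 0.862 to 1.11 over all libraries. Scores of exactly 0 or 100 made up 6.35% (95% Wilson interval 3.67 to 10.8) and 6.28% (3.63 to 10.7) of X sites in the wild type libraries, against 0.997% and 0.906% of autosomal sites. In the knockout libraries they made up 0.524% (0.0925 to 2.91) and 1.05% (0.288 to 3.74) of X sites, against 0.798% and 1.70% of autosomal sites. With libraries as the unit, the exact permutation test on the ratio of spreads gave p = 0.333, its smallest value.

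**Figure D4:**
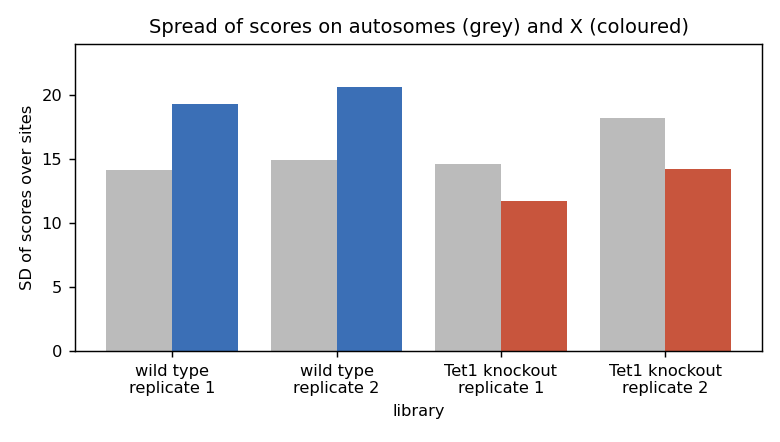
SD of scores over sites (vertical axis, score units) on autosomes (grey bars) and on X (coloured bars) in each of the 4 libraries (horizontal axis). X is wider than the autosomes in both wild type libraries (19.3 and 20.6) and narrower in both knockout libraries (11.7 and 14.3).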

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

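The single library constant, the simple ratios between constants, the analyses without X and Y, the log2 scale combined with the filter, the counts of sites below 50 in 1 genotype alone, the contrast of X with the autosomes, and the test of runs with its alternatives were chosen after seeing the data. All alternatives started from the same list, whose sites follow a rule on the scores of all 4 libraries, so they do not test the effect of that rule. The mean difference between genotypes was positive under all 8 alternatives (2.30 to 4.002) and the median difference under all 7 (2.51 to 3.99). The excess of higher over lower sites was positive under all 8 (3.89 to 19.2 percentage points, the lowest after median centring and the highest without knockout replicate 2). The share of sites above 0 differed by -0.145 percentage points and reversed to 0.0363 with a floor at the 10th percentile of positive scores. Leaving out libraries moved it from -0.644 to 0.353, the latter without knockout replicate 2. The mouse number used as a replicate block raised the sites called from 0 and 0 to 20 higher and 17 lower in the knockout, all 4 named sites among them. Under the other 8 alternatives run for the named sites none passed. The numbers are not stated to pair mice, and the differences between replicates 1 and 2 of the genotypes were hardly correlated across sites (r = -0.0210). On the log2(score + 1) scale 248 sites were called higher and 152 lower, and 316 and 190 with only sites above 0 in all 4 libraries. The cause was not tested. The other 11 alternatives in each direction, leaving out libraries included, called 0 sites. Leaving out 1 library gave 2223 to 3677 sites below 50 in the wild type alone and 1331 to 2210 in the knockout alone, because the criterion then asks for fewer libraries: the wild type count was 3466 without knockout replicate 1 and 3677 without knockout replicate 2, and the knockout count 2210 without wild type replicate 1 and 2056 without wild type replicate 2. The runs called, 5 higher and 1 lower, became 0 and 0 with the replicate block, without a trend and without each library in turn (0 to 0 in both directions), 3 and 4 with quantile normalization, 0 and 1 with median centring, 5 and 0 on the log2(score + 1) scale, and 4 and 1 with a single constant, and the cause was not tested. A library left alone in its genotype is assumed by limma to vary like the other genotype. X minus autosomes stayed negative under all 7 alternatives (-7.04 to -2.62, the latter the highest over simple ratios between the constants), and 19 of 19 autosomes kept a higher knockout mean under the 6 alternatives run. Those 6 did not include median centring or quantile normalization. The unknown depth per site limits what a single score can show. A second count test with its size factors, a higher coverage minimum, a wider promoter and the alternatives of the gene-list tests were not run, since they need counts, coverage or genes of the same build.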

Other observations

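The tests of a single library constant, without the combinations of ratios, and of leaving out a library were set before their results were seen, and the other tests in this part were chosen after the result was seen. Read with low scores as 5hmC, the wild type alone would carry it at 2223 sites and the knockout alone at 1331, and read the other way the sites would belong to the opposite genotype. Differences between genotypes at neighbouring sites no more than 200 bp apart were correlated (r = 0.191, 95% bootstrap interval 0.0962 to 0.284, 396 pairs, p = 0.0003 against random partners), and the difference between the wild type replicates was correlated to a similar degree (r = 0.210, interval 0.0992 to 0.321, p = 0.0001, the smallest these draws can give). The same correlation for the knockout replicates was 0.0749 (p = 0.13), and between 200 and 1000 bp the genotype correlation was 0.0916 (p = 0.14).

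The X chromosome departed from the autosomes in mean and spread, and the spread followed genotype. Chance among chromosomes is argued against by the adjusted permutation p of 0.0012 over sites. The ratio of X to autosomal spread lay outside the autosomes' range in 4 of 4 libraries. It cannot decide about a library-wide change in noise, because the listing rule ties the scores of both genotypes at a listed site. X also held fewer sites (189) than any autosome (258 or more), so that range is not matched for size. At the listed sites the X minus autosome difference was -5.50 with a single constant, and -6.37 to -2.62 over 625 combinations of simple ratios between the constants. Unequal library constants stay open all the same, because with a single constant 522 listed sites would break the listing rule, while sites that would enter are not listed. A candidate explanation, also open, is that the wild type mice had 1 X and the knockout mice 2, with the wild type ratios of spread at 1.36 or more. The knockout ratios of 0.803 and 0.782 lay below the autosomes' range of 0.862 to 1.11. That explanation was set to need knockout ratios inside this range, so this part of its prediction failed. Neither the wild type nor the knockout ratios decide it, because the listing rule ties the scores of each genotype at a listed site to the other's. In the knockout libraries 70.2% and 77.0% of X sites were below 50, against 61.9% and 63.9% of autosomal sites. In the wild type libraries 67.7% and 66.0% were, against 78.8% and 77.4%. How far the rule shapes the mean and spread on X was not tested. On Y, 4 of 10 knockout values were blank and 0 of 10 wild type values, although knockout scores were still given at Y sites, so the sex of the mice stays open, as does an effect of Tet1 loss on X itself.

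The excess of sites below 50 in the wild type alone stood at a ratio of 1.67 to those in the knockout alone, and no explanation for it could be excluded. Models with the library-wide shares below 50 reproduce an excess in this direction. Those shares were fitted to the same counts, so this is not an independent account of the excess. Independent libraries under the rule gave 1998 against 1012 sites, and the model with the shared site level term 2326 against 1228. That term cannot separate a shared level from site-specific genotype differences. The observed knockout count, 1331, lay above both expectations, and the wild type count, 2223, between them. Unequal library constants stay open, although a single constant gave a ratio of 1.77, because 522 listed sites would then break the listing rule while sites that would enter are not listed. A single deviating library stays open too, although the lowest ratio over the 4 pairs of 1 wild type and 1 knockout library was 1.57, because the listing rule lets 1 library shape which sites enter and so moves every pair. The ratio without wild type replicate 1 was 1.01 and without wild type replicate 2 was 1.08, against 2.60 and 2.76 without knockout replicate 1 or 2, but that test decides nothing, because it asks 1 library of one genotype and 2 of the other. The genotype, and any other difference that goes with it such as sex, may account for the excess and was not separated from these, although on the autosomes alone the ratio was 1.69.

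At 55.2% of sites both knockout scores lay on one side of both wild type scores, which may come mostly from how the list was made and from library-wide differences. Independent libraries kept by the listing rule gave a mean of 54.1% (highest of 20 draws 54.96%), so the observed share exceeded the simulated one only slightly. The rule with library-wide differences cannot be told apart from site-specific differences by this share. The counts of below-50 patterns are another matter, since their deviance of 597 argues against fully independent libraries. The model with the shared site level term left a deviance of 54.3 on 1 degree of freedom, with unequal noise between libraries as an open reason. That term cannot tell a level shared by all 4 libraries from site-specific genotype differences. Scores at sites outside the list would be needed to estimate the genotype effect without the rule.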
